A study of Mus musculus with 4 samples.

How the data were processed

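NKT cells of WT and PLZFon C57BL/6 mice were sorted from thymus by CD1 tetramer binding. Their DNA was released by proteinase K at 50 °C over 12 to 18 h and sonicated to a median length of 180 to 230 bp, per the labels' protocols. There were 4 libraries, 1 per group (WT MeDIP, PLZFon MeDIP, WT input, PLZFon input), grouped by their titles. The antibody label conflicts with the titles, since it gives none for PLZFon MeDIP and anti-5-methylcytosine for WT input.

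BWA and edgeR are named in the submitters' processing notes, with the mm10 build and no versions. Sorted and unique-filtered alignments are named per the file headers. The deposited table holds raw counts of reads per window of 100 bp for each library. It also holds RPKM values that the authors computed from those counts, a relative methylation score from the authors for each MeDIP library, and a CpG factor, a score of the CpG content of the window, which ran from 1 to 20. The authors' edgeR columns give log2 fold changes, PLZFon over WT as their sign against the counts shows, with deposited p-values and adjusted p-values. The listed windows all had at least 10 reads over both MeDIP libraries and a CpG factor of at least 1, as tested on the table. With its header the table has 1048576 lines, the row limit of a spreadsheet, and it ends within chromosome 7. A window that is not listed is not a window without reads. Regions beyond it, and with them the sex chromosomes and the T cell receptor alpha locus, were not analysed here.

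Library totals were recovered from the ratio of counts to RPKM, and they ranged from about 10635946 to 60689327 reads. They were the main scaling. A ratio is the PLZFon share of reads over the WT share, with an exact (Clopper-Pearson) 95% interval of the binomial share. PCR duplicates and differences between animals are not covered by these intervals. Fold values against 0 reads used a floor of 3 reads in the library, which is less strict than the exact interval printed beside them. In the inputs the scaled squared difference between windows rose little from a distance of 4 to 8 windows (PLZFon 1.142 to 1.192, WT 1.153 to 1.224). In the MeDIP libraries it rose further, from 3.349 to 3.983 in PLZFon and from 3.407 to 3.637 in WT. A read was taken to be counted in about 4 windows, which is less certain for MeDIP. Sums over windows were divided by 4 to give reads over a locus. Only listed windows were summed, so reads are understated where a read fell in fewer than 4 listed windows.

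The gene table used here is of the same primary assembly as mm10 (GRCm38.p6) and gives no strand. Planned promoters were therefore replaced by the annotated gene with 1000 bp on each side, a change made after the files were seen. Gene lists, the rule of size and the rule for named genes were fixed before the data were examined. All 275 symbols of the 16 lists matched the gene table and 117 lay in the range of the table. A window or locus passed the rule with at least 20 reads over both libraries, a ratio of at least 2 in either direction and an interval excluding equality. The named loci were the 10 highest and 10 lowest that passed (7 higher ones existed), all list members that passed or the 2 largest by absolute log2 ratio with at least 20 reads, the 3 highest and 3 lowest windows, and for the control lists the 2 members with the most and the least MeDIP over input. Further list members, such as Bach2, Stat4, Gata3 and Hdac4, were named outside the rule for named genes. List medians were taken over loci with at least 10 reads and placed among 10000 random lists matched on read number. Backgrounds were the same rule on the inputs and simulated counts with no difference (20 rounds for loci).

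With no replicates there was no test of genotype and no p-value was computed. The rule was tested on simulated data at the real depths of the 7668 loci: it recovered 46% of loci changed 2-fold, 95% of loci changed 3-fold and 0.482% of unchanged loci. The authors' p-values were compared with edgeR exact tests on 3500 windows, and a dispersion of 1e-04 brought 99.7% within 0.01 on the log10 scale. Alternatives were TMM factors, scaling within CpG factor classes, other read minimums, ratios and flanks, windows with similar inputs and stricter thresholds on the authors' table. Alternatives added after seeing the data were the removal of windows with at least 60 input reads, scaling by the listed windows and windows within 1000 bp of gene ends.

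The tests of explanations in the closing section were all chosen after their results were seen. Those for the blocks of chromosomes 2 and 6 were first run on the called windows, which had been selected for their ratio, and were then replaced by tests on all listed windows of each block, the one beside Rn4.5s being split at a CpG factor of 7, a bound near the mean factor of the called windows (7.72). The test of CpG-rich enrichment over Lef1 was first whether scaling within CpG factor classes ended the 1.5-fold call, which it did; TMM factors ended it too, so that test could not separate the trend from the overall scaling and was replaced by the lowest ratio of any CpG factor class. The bound of 100 reads for loci was likewise set late. R 4.3.3, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.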

Results

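DNA methylation was profiled in natural killer T (NKT) cells, T cells that recognise lipids presented by CD1d, sorted from mouse thymus with CD1 tetramers. MeDIP-seq was used, in which sonicated DNA is pulled down with an antibody against 5-methylcytosine and sequenced beside DNA that was not pulled down (input). One MeDIP library and 1 input library were made from wild-type (WT) C57BL/6 mice and likewise from mice named PLZFon. PLZF, encoded by Zbtb16, is the transcription factor that directs NKT cell development, and the series concerns how the acetylation of PLZF affects NKT cell differentiation. The labels do not describe the PLZFon allele. With 1 library in each of the 4 groups there are no replicates. All 95% intervals are exact binomial intervals that cover counting error only, and every difference is one between 2 libraries, not between genotypes.

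The libraries held about 15143451 reads (WT MeDIP), 10635946 (PLZFon MeDIP), 60689327 (WT input) and 50365402 (PLZFon input), as recovered from the deposited values. The table used here listed 1048575 windows of 100 bp (mm10) on chromosomes 1 to 6 and on chromosome 7 up to position 139972600. Each listed window held at least 10 reads over the 2 MeDIP libraries. Zbtb16 and the NKT effector genes Il4, Il13, Ifng and Tbx21 lie on other chromosomes and were not analysed here.

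The first comparison asked whether the pull-down enriched methylated DNA in both genotypes. Windows rich in CpG, the site of most mammalian DNA methylation, were pulled down more strongly in both MeDIP libraries and not in the inputs. In WT cells the depth-scaled MeDIP reads were 3.68 times the input in windows with a CpG factor (the authors' CpG score of a window) of 1 and 7.36 times in windows with a factor of 7 or more. In PLZFon cells these values were 3.56 and 6.72. Windows were listed only with at least 10 MeDIP reads, whatever their input, so the selection can raise all of these values. The PLZFon input went only from 0.194 to 0.241 depth-scaled reads per window (RPM) and the WT input from 0.191 to 0.236. The library titled PLZFon MeDIP was therefore enriched like the WT one, although a label gives no antibody for it and gives the antibody for the WT input.

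PLZFon cells had slightly fewer MeDIP reads than WT cells over the listed windows, with a ratio of 0.964 (95% interval 0.963 to 0.966), and the gap was wider in CpG-rich windows. The ratio was 0.985 (0.982 to 0.988) at a CpG factor of 1 and 0.928 (0.922 to 0.934) at a factor of 5, while the inputs stood at 1.01 over all listed windows. Windows within protein-coding genes (0.96), within other genes (0.971) and outside genes (0.967) had similar ratios, and the chromosomes ranged from 0.958 for chromosome 7 to 0.975 for chromosome 6. Windows with at least 60 input reads, 3 times the median of 20, stood apart at 1.15 (1.13 to 1.16), with an input ratio of 1.09 (1.08 to 1.1). A scaling by all reads cannot separate a small shift in methylation from a small difference in pull-down efficiency.

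The second comparison asked which windows differed between PLZFon and WT MeDIP. Single windows far apart in the 2 libraries lay in Ptgir, the prostacyclin receptor gene, in the phosphatase gene Inpp4a and in Gm13241 on the higher side, and in Fhad1 and Nenf on the lower side. In Ptgir (chromosome 7, 16907301 to 16907400) there were 21 PLZFon reads and 0 WT reads, at least 9.97-fold higher with WT set to a floor of 3 reads, while the exact interval of the ratio starts at 7.41, with 14 and 11 reads in the PLZFon and WT inputs. In Gm13241, which overlaps Vmn2r-ps16 there (chromosome 4, 146475201 to 146475300), there were 43 against 5 reads, a ratio of 12.2 (4.86 to 39.6), with 43 and 42 input reads. In Inpp4a (chromosome 1, 37391901 to 37392000) there were 19 against 2 reads, a ratio of 13.5 (3.26 to 120).

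In the other direction, a window shared by Fhad1 and Gm35295 (chromosome 4, 141930101 to 141930200) had 0 PLZFon and 29 WT reads, at least 6.79-fold lower at the same floor, with an exact interval of the ratio from 0 to 0.193, although its inputs also differed, with 3 and 15 reads. Adjacent windows in Nenf, which encodes a secreted neurotrophic factor (chromosome 1, 191317301 to 191317400 and 191317401 to 191317500), had 0 against 22 and 0 against 21 reads, at least 5.15-fold and 4.92-fold lower at that floor, with exact intervals of the ratio from 0 to 0.26 and from 0 to 0.273. Windows less than about 4 apart share reads, so these Nenf windows are 1 observation. Windows in Ccz1, Rab43 and Ccdc30 also had 0 against 21 reads, and the second Nenf window was named because it came first in genome order.

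Of 409114 windows with at least 20 MeDIP reads, 4618 were at least 2-fold higher in PLZFon and 8876 at least 2-fold lower with an interval that excluded equality, 3.3% together. Chance sampling of the same reads with no difference gave 5178 and 5931 windows (2.72%), and the 2 inputs, compared by the same rule, gave 10665 and 7948 of 554402 (3.36%). Scaling with TMM factors turned the split to 7377 higher and 7101 lower. Sampling that also carried the drift of the ratio with read number gave 3757 and 8182.

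The third comparison asked which gene loci, taken as the annotated gene with 1000 bp on each side, differed in MeDIP reads. Flg, which encodes the skin barrier protein filaggrin, had the highest ratio of the protein-coding loci that passed the rule. Lef1, the transcription factor gene of early T cells, had the lowest ratio of the protein-coding loci with at least 200 reads, a bound that was not planned. Flg (chromosome 3, 93273546 to 93293689) stood at 3 times the WT level (2.19 to 4.17), from 124 PLZFon and 59 WT reads over 54 listed windows. The ratio was not even along Flg: 2 of 3 bins of 10 kb lay above 1, up to 4.29 (2.7 to 7.01), the other had 0.583 (0.229 to 1.35), and a bin outside the gene (93320001 to 93330000) had 1.36 (1.11 to 1.66). Its input ratio was 1.12 (0.928 to 1.35), and its windows held 34.6 input reads on average against 21.1 in windows without raised input. MeDIP reads over Flg were 0.99 times the input in WT and 2.64 times in PLZFon. Both were below the values over all listed windows (4.44 in WT and 4.22 in PLZFon).

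Lef1 (chromosome 3, 131110297 to 131224357) had 326 PLZFon and 814 WT reads, a ratio of 0.571 (0.5 to 0.65), which is below equality but under the 2-fold size asked by the rule. Its input ratio was 0.969 (0.861 to 1.09). Within 1000 bp of the gene ends alone the MeDIP ratio was 0.787 (0.439 to 1.38), an interval that includes equality. MeDIP reads over Lef1 were 5.1 times the input in WT and 3.01 times in PLZFon. The ratio lay below 1 in 12 of 12 bins of 10 kb across Lef1, with an interval below 1 in 9 of them. In 40 bins of the flanking sequence the median ratio was 0.944, and 1 interval excluded equality. Among 3556 protein-coding loci with at least 200 reads Lef1 was the lowest (log2 ratio -0.81), followed by Ruvbl1 (-0.64), a chromatin remodelling ATPase gene, and Ccm2l was the highest (0.56). Loci with fewer reads, such as Fam136a (-1.78), had lower ratios.

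**Figure D1:**
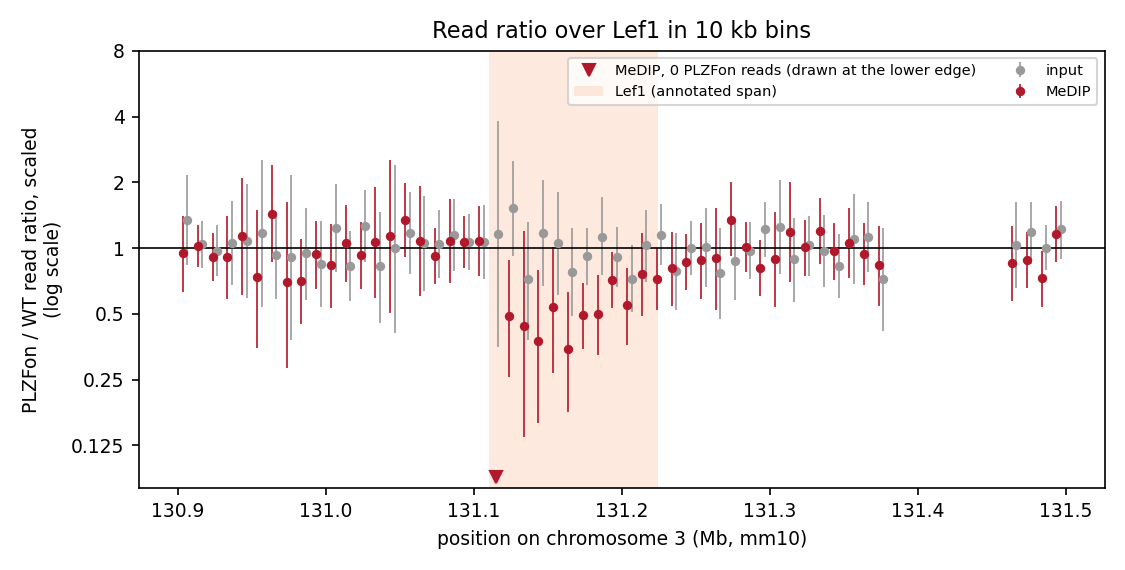
PLZFon over WT read ratio (log scale) in 10 kb bins along chromosome 3 (Mb, mm10), for MeDIP (red) and input (grey), with the Lef1 gene shaded; points are 1 library against 1 library and bars are exact 95% counting intervals. MeDIP ratios lie below 1 in 12 of 12 bins of Lef1 and around 0.944 in the 40 bins outside it; 1 bin with 0 PLZFon reads is drawn as a triangle.

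Of 7668 protein-coding loci with at least 20 reads, 7 were at least 2-fold higher and 27 at least 2-fold lower with an interval excluding equality. Simulated libraries with no difference gave 19.9 and 27.7 such loci, and TMM factors gave 9 and 19. Besides Flg, the higher loci were Fasl, the Fas ligand gene of cytotoxic cells, at 2.79 (1.03 to 8.4), the oocyte factor gene Figla at 2.33 (1.01 to 5.65), Gm2004 at 2.25 (1.07 to 4.9), the NK receptor gene Klrb1b at 2.12 (1.14 to 4.01), the chemokine gene Cxcl9 at 2.08 (1.01 to 4.45) and Spef1 at 2.05 (1.15 to 3.71). Fasl rested on 13.2 and 6.75 reads.

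The lowest 10 of the 27 were Fam136a at 0.266 (0.0701 to 0.761), Aqp11 at 0.295 (0.0771 to 0.857), Nagk at 0.293 (0.064 to 0.948), H2al2a at 0.345 (0.116 to 0.863), Rnf133 at 0.349 (0.12 to 0.858), Coro1a at 0.356 (0.128 to 0.847), Gm13889 at 0.392 (0.181 to 0.778), Pnrc1 at 0.387 (0.142 to 0.917), Clec2e at 0.394 (0.137 to 0.967) and Vps37d at 0.419 (0.159 to 0.973). Coro1a, an actin regulator gene of leukocytes, and Gm13889 also had low input ratios, 0.563 (0.278 to 1.09) and 0.575 (0.248 to 1.25). The 7 higher and 27 lower loci do not exceed the simulated numbers. Reads over a locus are understated where a read fell in few listed windows. The simulation drew on these read numbers, so it can give too many passing loci. The comparison with simulated numbers therefore cannot decide whether single members differ beyond counting error.

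Flg and Lef1 were the loci whose whole interval lay beyond 1.5-fold, a rule that was not planned. For Lef1 this call ended with TMM factors (0.592, 0.519 to 0.674), with scaling by the listed windows (0.592, 0.519 to 0.674) and with scaling within CpG factor classes (0.596, 0.523 to 0.679), all still below equality. Simulation gave 0.95 higher and 1.25 lower loci of that kind. Among the 5297 loci with at least 100 reads, a bound chosen after both loci had been seen, it gave 0.05 and 0. Over the 3556 loci with at least 200 reads the SD of the log2 ratio was 0.153, against 0.144 from counting alone, and 88.6% lay within 1.2-fold of equality.

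**Figure D2:**
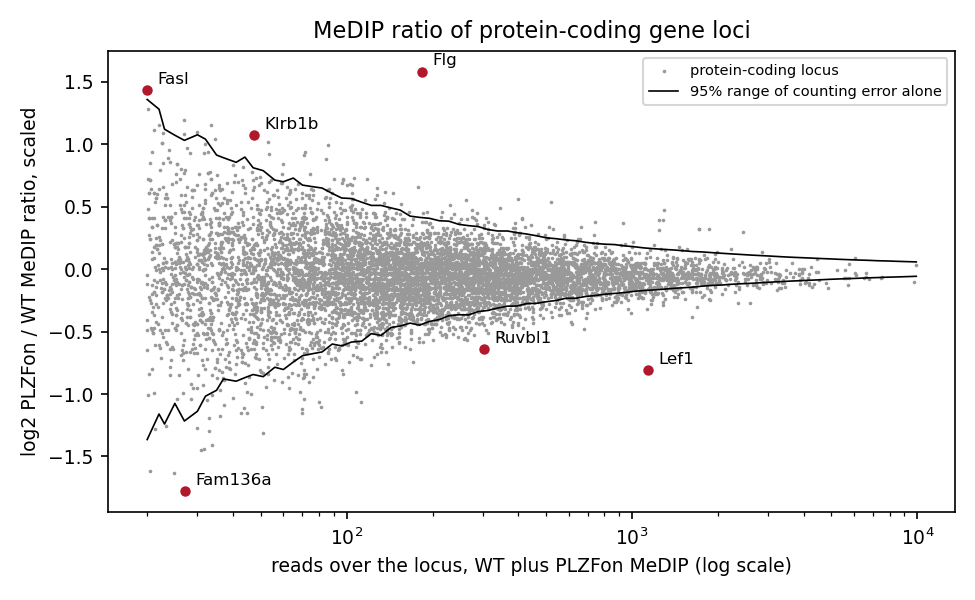
Log2 PLZFon over WT MeDIP ratio of protein-coding loci against the reads over the locus in both MeDIP libraries (log scale); each point is 1 locus and the lines enclose 95% of values under counting error alone. Flg (1.58) and Lef1 (-0.81) lie far outside the lines for their depth, while Fasl and Fam136a rest on few reads.

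The fourth comparison asked whether gene groups of NKT cells differed between PLZFon and WT MeDIP. The NKT lineage regulators had a median log2 ratio of -0.01 over 12 measured loci, at percentile 81.8 of random lists matched on read number, and 0 of them passed the 2-fold rule. Bach2 (0.00), Tox (0.00), Nfkb1 (-0.01) and Hivep3 (-0.02), transcriptional regulators of T cells, lay at equality. Lef1 had -0.81, and Id3, an inhibitor of E proteins, had -0.85 on 7 and 18.8 reads, with a ratio of 0.532 (0.189 to 1.32). The other members ranged from -0.25 (Slamf1) to 0.13 (Cd44), all with intervals that include equality. The NKT2 genes, of the subset that makes interleukin 4, had a median of -0.18 over 7 loci (percentile 8.62) and 0 passing. Lef1 and Plac8, at 0.692 (0.502 to 0.945), had its largest differences. Gata3, the regulator of that subset, had 0.45, with an interval of the ratio (0.78 to 2.38) that includes equality.

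The NKT1 genes, of the subset that makes interferon gamma, had a median of -0.1 over 9 loci (percentile 34.5), and Fasl alone passed. Stat4, which relays interleukin 12 signals, had 0.29 and Il12rb2, a receptor chain for it, had -0.14. The NKT17 genes, of the subset that makes interleukin 17, had a median of -0.04 over 8 loci (percentile 56.3) with 0 passing, and the largest differences with at least 20 reads were at Tmem176a (-0.45) and Il23r (0.43). The cytokine genes had a median of 0.06 over 7 loci (percentile 71.9) with 0 passing, and Il17a (0.22) and Tgfb1 (-0.12) differed most among members with at least 20 reads. Of the NKT1, NKT17 and cytokine genes named here, only Fasl had an interval that excluded equality.

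The PLZF partners and acetylation enzymes had a median of 0.13 over 6 loci, at percentile 98.3 and above the middle 95% of random lists (-0.23 to 0.11), the only one of the 15 lists with a percentile for which this held. None passed the 2-fold rule. Bmi1, a Polycomb gene, had 1.61 (1.07 to 2.42) and its input ratio was also high at 1.8, while the deacetylase genes Hdac1 and Hdac4 had log2 ratios of -0.25 and 0.14. At the gene ends alone the median was 0.79. The DNA methylation machinery had a median of -0.03 over 5 loci (percentile 61.5) with 0 passing, with Gadd45a at 0.19 and Tet2, which oxidises 5-methylcytosine, at -0.15. The intervals of Hdac1, Hdac4, Gadd45a and Tet2 include equality.

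Lists for other cell types were compared in the same way. A ratio of MeDIP reads between 2 libraries does not measure which cells the sort held. The T cell identity genes had a median of -0.08 over 7 loci (percentile 40.7), with Cd28 at -0.65 and Cd2 at 0.33, and the genes of other thymocytes had 0.00 over 7 loci (percentile 68.2), with Rag2 at 0.63 and Cd8a at -0.26. The B cell markers had -0.25 over 6 loci (percentile 4.21), with Cr2 at -0.52 and Cd79a at -0.34, and the myeloid markers -0.15 over 5 loci (percentile 18.1), with Fcgr3 at 0.21 and Itgam at -0.17. None of the loci in these 4 lists passed the rule, and the intervals of the members named from them all include equality. The NK cell markers had 0.19 over 4 loci (percentile 81.8), and Klrb1b passed. Of the thymic epithelium markers only Ly75 was measured (-0.10).

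The control lists did not separate over whole loci. Germline genes, whose promoters are methylated in somatic cells, had a median MeDIP over input of 4.18 in WT and 3.48 in PLZFon, against 3.96 and 3.99 for housekeeping genes. Among germline genes in WT, Slc25a31 (5.6) and Tuba3b (4.6) had the most and Sycp1 (2.8) and Asz1 (3.32) the least, and among measured housekeeping genes Gusb (4.65) and Psmb2 (4.41) had the most and Rplp0 (2.34) and B2m (3.59) the least. The median log2 ratio was -0.14 over 11 germline loci (percentile 17.7), with Slc25a31 at -0.63 and Asz1 at -0.5, and -0.08 over 6 housekeeping loci (percentile 44), with B2m at 0.21 and Psmb2 at 0.17. Imprinted genes had -0.02 over 10 loci (percentile 75.2), with Nap1l5 at -0.7, where the input ratio was 0.651, and Peg3 at -0.27. The intervals of the PLZFon over WT ratio of these germline, housekeeping and imprinted members all include equality.

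The fifth comparison was the authors' own. The authors' deposited table called 151 windows at an adjusted p below 0.05, of which 138 were higher and 13 lower in PLZFon. These counts cover the listed windows alone. The adjusted p-values in the authors' deposited table rest on another set of windows, since its smallest p of 1.1e-11 (in Gm13241) has an adjusted p of 6.27e-07, where Benjamini-Hochberg adjustment over the listed windows gives 1.15e-05. Among the 151, 74 lay in a block of 117 kb beside the RNA gene Rn4.5s (chromosome 6, 47655101 to 47772400), 18 in a block of chromosome 2 (98662301 to 98667300) and 14 in Gm40237 (chromosome 4, 118547101 to 118548500). Of the 151 windows, 115 had at least 60 input reads, and all 115 were higher in PLZFon. The other 36, by the authors' deposited table, were 23 higher and 13 lower.

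In the block beside Rn4.5s the called windows had a MeDIP ratio of 2.44 (2.23 to 2.68) and an input ratio of 1.61 (1.5 to 1.73). Over all 550 listed windows of the block, called or not, the MeDIP ratio was 1.35 (1.31 to 1.39) and the input ratio 1.25 (1.22 to 1.28), with a mean of 62.2 raw PLZFon and 65.7 raw WT MeDIP reads. In the block of chromosome 2 the called windows held 6898 raw PLZFon and 6879 raw WT MeDIP reads, and 6787 and 6775 input reads, and after scaling to depth the MeDIP ratio was 1.43 (1.33 to 1.53), close to the depth ratio of the libraries (1.42). Over all 31 listed windows of this block, called or not, the raw reads were 8995 and 8983 (MeDIP) and 9063 and 9059 (input). In Gm40237 the raw MeDIP reads were also almost equal, 4770 in PLZFon and 4800 in WT. Its inputs held more, 6378 (PLZFon) and 6290 (WT), so the 4 libraries did not share 1 level there. Calls without raised input included Ptgir, Zfp787, Clcn4, Inpp4a and a stretch 45449 bp from Chst1 (chromosome 2, 92660701 to 92661100; ratio 4.05, 2.26 to 7.63) on the higher side, and Slc13a4 (0.154, 0.0208 to 0.595), Ccz1, Nenf and Fhad1 on the lower side; they were selected here after their values were seen. The authors' p-values could be rebuilt from an edgeR exact test with a dispersion of 1e-04, which allows almost no spread between animals, so they compare 2 libraries.

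**Figure D3:**
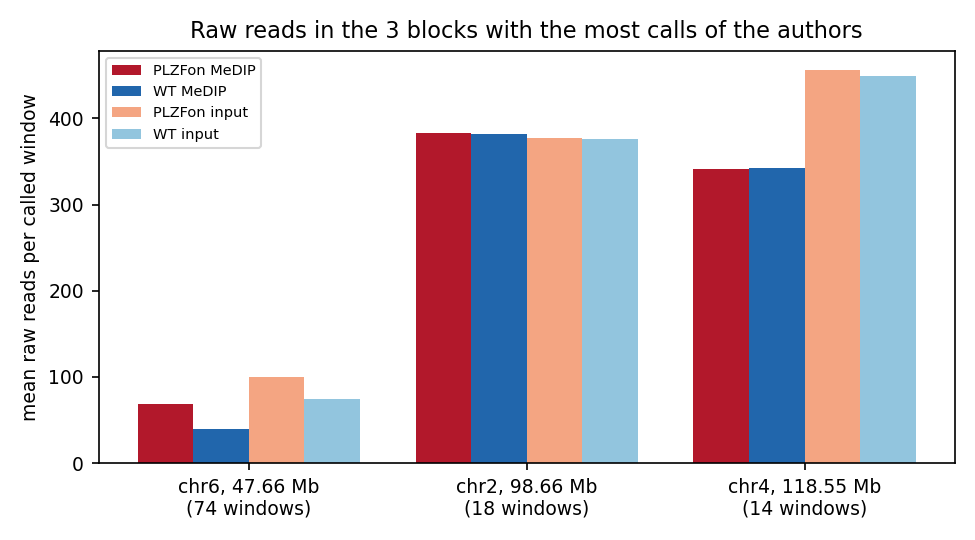
Mean raw reads per called window (not scaled to depth) of the 4 libraries in the 3 blocks with the most windows called in the authors' deposited table. In the blocks of chromosomes 2 and 4 the WT and PLZFon MeDIP bars are almost equal (6879 and 6898 reads in sum on chromosome 2), while on chromosome 6 the PLZFon MeDIP bar is higher.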

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

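The alternatives that drop windows of raised input, scale by the listed windows or use gene ends were chosen after seeing the data. Of the summary results, 28 values were labelled as moved and 118 were not. The cause was not tested beyond the construction of each alternative. Some of the 118 still changed in size or sign. With at least 20 reads the NK cell marker median went from 0.19 to 0.59 and the NKT1 median from -0.1 to 0.15. At gene ends the cytokine median went from 0.06 to -0.25. Windows higher in PLZFon (4618) became 7377 with TMM factors, 7503 with scaling within CpG factor classes, 7378 with scaling by the listed windows, 14541 at 10 reads, 190 at 50 reads, 1440 at 3-fold and 2863 with inputs within 1.5 times of each other. Windows lower in PLZFon (8876) became 16467, 730, 3842 and 5888 under the last 4 of these settings. Higher gene loci (7) became 2 at 50 reads, 30 at 1.5-fold, 1 at 3-fold and 15 at gene ends; lower loci (27) became 10, 76, 3 and 42. At gene ends the list medians moved to 0.13 for NKT lineage regulators, 0.79 for PLZF partners and acetylation enzymes, -0.25 for other thymocytes, -0.37 for myeloid markers and -0.27 for imprinted genes, on fewer windows per gene. Lef1 moved to -0.33 at its ends, where the interval (0.439 to 1.38) included equality, and Flg had no listed window there. The authors' 138 higher windows became 86 at an adjusted p below 0.01, 88 with a fold of at least 2 and 23 without windows of raised input; the 13 lower ones became 1 at an adjusted p below 0.01. The setting with autosomes only removed nothing. The planned values for sex chromosomes and the T cell receptor alpha locus were not run. No paired analysis was possible because each group has 1 library. At 8.8 (PLZFon) and 13 (WT) MeDIP reads per listed window on average, most single windows held too few reads for the rule: 409114 of 1048575 reached 20.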

Other observations

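Antigen receptor loci of chromosome 6 gave values outside the comparisons. The T cell receptor beta D, J and C segments (41533201 to 41548181) had 0 listed windows in 15 kb, and the V segments had 147, or 0.376 per kb. The immunoglobulin kappa V segments had 1492 (0.474 per kb) and the J and C segments 16 (3.82 per kb).

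The following tests were all chosen after the result was seen. The first pattern is the lower MeDIP signal over Lef1. A loss of copies in PLZFon DNA is argued against by the input ratio of 0.969 (0.861 to 1.09), above the MeDIP interval of 0.5 to 0.65, and a few pileups by the ratio of 0.564 (0.486 to 0.654) without the tenth of windows with the most WT reads. Weaker enrichment of CpG-rich DNA in the PLZFon library is argued against as the whole cause, since no CpG factor class had a ratio below 0.924 (0.915 to 0.933), but it may contribute a part. Another mix of NKT subsets in the sort cannot be told apart from a change within cells. Without Lef1 the NKT1, NKT2 and NKT17 lists stood at percentiles 34.5, 29.5 and 56.3 of random lists. They held 9, 6 and 8 measured loci, too few to decide. The PLZFon genotype itself remains an untested explanation, with 1 library per group.

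The second pattern is the set of the authors' calls in windows of raised input, all of them higher in PLZFon. On chromosome 2 the raw WT over PLZFon MeDIP reads were 0.999 over all 31 listed windows of the block and the 4 libraries lay within 1.01 times of each other although their depths differ, which is consistent with a ceiling on distinct reads per window that scaling to depth turns into a PLZFon excess. Beside Rn4.5s, 121 windows had a CpG factor of 7 or more and held 36 of the 74 calls. Of these windows, 67.8% had more raw PLZFon than WT reads beyond counting error. The bound of 7 was set near the mean factor of the called windows, so this class can still carry their selection. Neighbouring windows share reads, so the 67.8% counts dependent windows. The input ratio of the class, 1.33 (1.26 to 1.41), lay below its MeDIP ratio of 1.88 (1.73 to 2.04). With these limits, the values argue against a ceiling or more copies in PLZFon DNA as the whole cause there. In the 429 windows with a lower factor, which hold the other 38 calls, neither can be told apart: 14% had more raw PLZFon than WT reads beyond counting error, and the input ratio of 1.23 (1.19 to 1.26) overlapped the MeDIP ratio of 1.28 (1.24 to 1.33). Methylation of this block, or reads shared between its copies, was not tested.

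The third pattern is the authors' relative methylation score, with a mean of 0.625 in WT and 0.57 in PLZFon. The score was higher in WT in 77.5% of windows, whereas the depth-scaled WT reads were higher in 52.4%. At equal raw count and CpG factor both libraries had the same score within 0.02 in 100% of 1145 pairs, which is consistent with the explanation that the score is not scaled to depth. No biological explanation was tested for it.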
